A study of Mus musculus with 6 samples.

How the data were processed

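RNA was measured in 6 libraries of mouse fibroblasts, 1 for each combination of 3 origins (lung, cardiac and tail tip) and 2 adenoviruses (Ad-GFP and Ad-Cre). Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, harvested 48 h after transduction and lysed in TRIzol, and polyadenylated RNA was sequenced. The values are whole-number read counts per Ensembl gene as deposited by the authors, with no normalisation. The submitters' processing notes name the mm39 genome build and STAR 2.0.7, without saying what each was used for. The counting tool, the annotation release, the strand setting and any filter are not given in the sources used here. Reads of a gene and of an overlapping antisense gene may therefore be mixed, and counts of genes with near-identical copies are uncertain.

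The table held 57180 gene identifiers, of which 35114 had at least 1 read and 0 named no gene. Symbols came from a reference gene annotation of an earlier mouse build (GRCm38), which matched 51884 identifiers and left 5296 without a symbol. Those stayed in all tests under their identifier. Another 66 repeated symbols were kept apart by identifier. That annotation is not of the build the counts use, so no coordinates are given. All 6 columns of counts were used, and each was matched to its library by the column name in that library's label. The labels say that these columns belong to a matrix whose title names another subject than the deposited table, so whether that table is the one meant rests on the column names alone.

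Total counts were 29535869 (lung Ad-GFP), 26170316 (lung Ad-Cre), 33779069 (cardiac Ad-GFP), 30034441 (cardiac Ad-Cre), 31004119 (tail tip Ad-GFP) and 32316417 (tail tip Ad-Cre). A gene with 0 reads can have up to 3 counts at these depths, which is between 0.0888 and 0.115 CPM. Between 22665 and 27267 genes had a read in a library. Without molecular identifiers reads are not independent molecules, so intervals and floors cover counting error only.

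Genes were tested with edgeR 4.0.16 in R 4.3.3. Low genes were removed with filterByExpr (minimum count 10), which left 18143. Libraries were scaled with TMM factors between 0.964 and 1.03. Robust quasi-likelihood F-tests used 1 additive model of origin and virus over all 6 libraries, with 2 residual degrees of freedom, a median prior of 5.12 degrees of freedom and a common dispersion of 0.0455. The virus effect was tested as a change common to the 3 origins, with origin as the block, and the difference between origins in their response is its residual. The origins were compared pairwise in the same model. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. The tests of genes and gene lists were two-sided.

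Within an origin no test was made. Ratios are of CPM (counts per megaread of library size, scaled with TMM factors), with exact conditional binomial 95% intervals, and log2 ratios have a prior count of 2. A ratio against 0 reads is a lower bound, computed against a floor of 3 counts over the group. Correlations of the log2 ratios were computed across genes. Principal components used log2 CPM with the same prior count over the 500 most variable genes.

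A set of 29 gene lists was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation and with fry. With an estimated correlation camera has only the 2 residual degrees of freedom of the model, so hardly any list can pass. A call lost there does not decide against a list. Members were counted from the test over all genes and from p-values adjusted over the list alone. Within an origin a list's median log2 ratio was placed among the medians of 10000 random lists of the same size, matched in 20 bins on mean expression over the 6 libraries. Some genes stand in more than 1 list, among them Gata6, Krt19, Des, Sox9, Wt1, Atf3 and Sesn2.

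The comparisons, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where a choice is said to be later. The rule names genes with a symbol that is not a bare identifier, a Gm number or a Rik name. It takes Gata4 and the GATA family, and for the virus comparison the 10 largest changes in each direction that pass. Where fewer pass, it fills up to 10 with the smallest unadjusted p among genes with a mean of at least 5 CPM and the same direction in all 3 origins. Within an origin it takes the 5 largest log2 ratios in each direction among genes with at least 50 reads in a library. For each origin it takes 8 genes that are higher than in both others, with at least 10 CPM there and the largest smaller fold change. Of each list it takes up to 4 examples per comparison with the largest absolute fold change and a mean of at least 1 CPM. Not every gene that the rule takes is printed.

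Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, library totals without TMM factors, no filter beyond 1 read, a mean of at least 5 CPM, a fit that was not robust, no origin or no virus term, a prior count of 0.5, and each library left out in turn. limma-voom with sample weights, and list members with at least 10 reads, were added after the data had been seen.

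The tests were checked on simulated data. In the virus comparison 77 of 100 genes with a log2 change of 1 and 92 of 100 with a log2 change of 2 were called among 17250 genes, with 26 unchanged genes called. In a comparison of origins 43 and 88 of 100 were called among 17390 genes, with 17 unchanged genes called. The unchanged genes were a larger share of these calls than the threshold of 0.05 names, and 0 changed genes had the wrong sign. The simulation gave all libraries 1 dispersion per gene and all origins the same virus effect. In the data the SD of the log2 ratios was 1.01 in the cardiac, 0.54 in the lung and 0.39 in the tail tip pair. The shares called therefore do not measure how often the test would find a real change. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 was used for ratios, intervals and figures.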

Results

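Polyadenylated RNA was sequenced from mouse fibroblasts of 3 origins, taken from the lung, the heart and the tip of the tail. Cells of each origin were infected with an adenovirus that carries either green fluorescent protein (Ad-GFP, the control) or Cre recombinase (Ad-Cre, described by the submitters as the GATA4 knockout), and RNA was collected after 48 h. Cre removes DNA that lies between its recognition sites, so a knockout needs cells with such sites in Gata4. The labels give the genotype of all 6 libraries as wild type and do not say which part of the gene was to be deleted. Each of the 6 groups holds 1 library, and total counts ran from 26170316 in the lung Ad-Cre library to 33779069 in the cardiac Ad-GFP library. With 1 library per group, a difference between the 2 libraries of an origin has no replicate check. Intervals given with such differences cover counting error only.

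The targeted gene was examined first. Gata4 (ENSMUSG00000021944), which encodes a zinc finger transcription factor of heart development, was abundant in cardiac fibroblasts, with a normalised count (CPM, counts per megaread of the library) of 147 in the Ad-GFP library and 149 CPM in the library labelled Ad-Cre. In lung fibroblasts it stood at 14.7 and 19.2 CPM, and tail tip fibroblasts held 1 and 2 reads of it, too few for a ratio. The ratio of the library labelled Ad-Cre to the control was 1.02 in cardiac fibroblasts (95% interval 0.978 to 1.06) and 1.31 in lung fibroblasts (1.14 to 1.49). Gata4 RNA was therefore not lower in either library labelled Ad-Cre. The deleted part is not given, and a count over the whole gene may miss the loss of a short part, so this value neither shows nor rules out recombination. All directions between the viruses are drawn from the labels.

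The other GATA factors and their cofactors differed more between the cardiac libraries than Gata4 did. Gata6, a close relative of Gata4, was at 86.6 CPM in the cardiac control and 43.1 CPM in the cardiac library labelled Ad-Cre, a ratio of 0.497 (0.466 to 0.531). Gata3 was at 8.58 and 4.19 CPM there, while Gata2 was at 14.2 and 16.1 CPM. Changes as large as those of Gata6 and Gata3 were common in the cardiac pair, where 20.3% of all tested genes differed at least 2-fold. In lung fibroblasts Gata6 had a ratio of 1.52 (1.30 to 1.77), Gata2 1.54 (1.38 to 1.71) and the cofactor gene Zfpm1 1.63 (1.46 to 1.82). Zfpm2, another cofactor gene, had a ratio of 1.02 in lung, 0.714 in cardiac and 1.06 in tail tip fibroblasts.

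**Figure D1:**
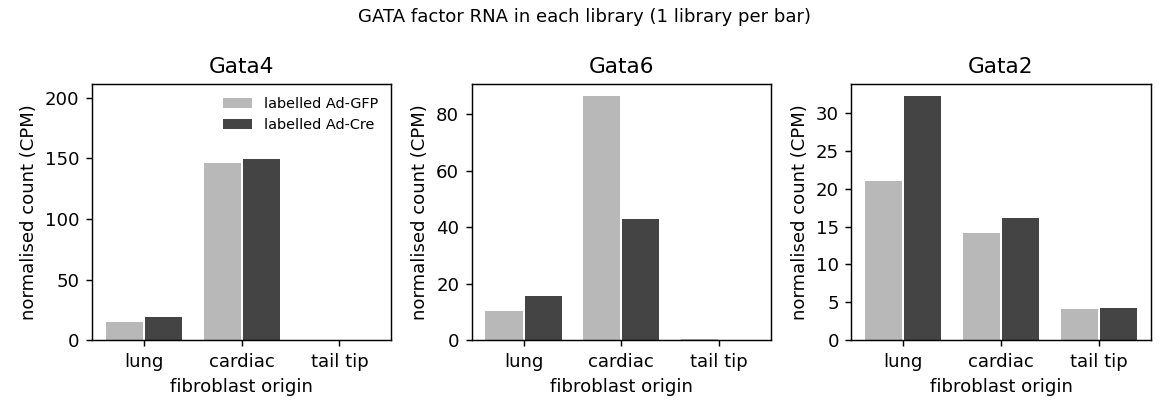
Normalised counts (CPM, linear axis from 0) of Gata4, Gata6 and Gata2 in each of the 6 libraries, by fibroblast origin; each bar is 1 library, light for Ad-GFP and dark for the library labelled Ad-Cre. Cardiac Gata4 is at 147 and 149 CPM, and cardiac Gata6 at 86.6 and 43.1 CPM.

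Fibroblast origin separated the libraries far more than the virus did. Over the 500 most variable genes, origin accounted for 98.1% of the sum of squares, the virus for 0.745% and the remainder for 1.14%. Over all 18143 genes tested the shares were 90.1%, 3.36% and 6.58%. The first principal component held 71.5% of the variance and the second 26.6%, and both libraries of each origin lay beside each other.

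**Figure D2:**
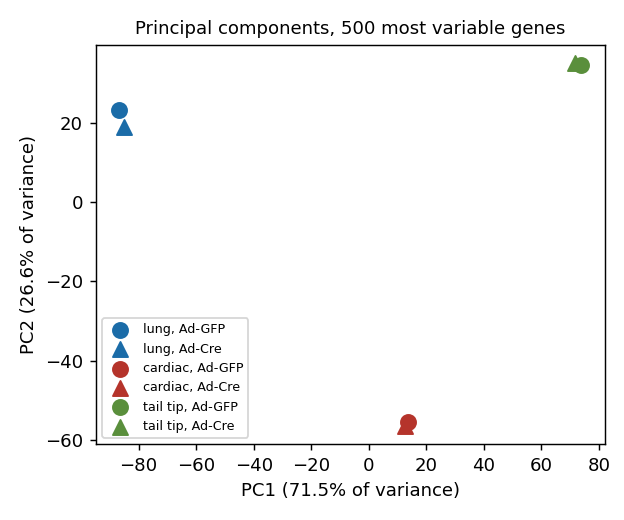
Positions of the 6 libraries on the first (71.5% of variance) and second (26.6%) principal components of log2 CPM over the 500 most variable genes; colours mark origin, circles Ad-GFP and triangles the libraries labelled Ad-Cre. The libraries group by origin.

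The comparison of Ad-Cre with Ad-GFP asks which genes differ in fibroblasts given Cre, as 1 effect fitted over the 3 origins. Macrophage and leukocyte markers were lower as a list in the libraries labelled Ad-Cre with a preset correlation (camera adjusted p = 6.6e-12), a call that was lost with an estimated correlation (adjusted p = 0.617). Cd68, a lysosomal protein of macrophages, had 846 and 454 reads in cardiac, 4966 and 3836 in tail tip and 59 and 36 in lung fibroblasts (control first). Cd14, the coreceptor for bacterial lipopolysaccharide, had 770 and 443, 8980 and 6862, and 349 and 209 reads in the same order. Epithelial markers (adjusted p = 8.0e-06) and mesothelial markers (6.3e-05) were higher as lists, which was also lost with an estimated correlation (adjusted p = 0.617 for both). The values differed by origin, and the epithelial list had a median log2 ratio of 2.44 in the cardiac pair and 0.03 in the tail tip pair. In the cardiac pair the keratin gene Krt18 was at 2.06 and 35.2 CPM, the desmosome gene Dsp at 6.61 and 57.6 CPM, and the mesothelial genes Upk1b at 5.66 and 41.5 CPM and Msln at 6.42 and 27.6 CPM. The mesothelial gene Lrrn4 went the other way, with 1048 and 288 reads. No single gene passed the edgeR test over the 3 origins.

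Among 18143 genes tested with edgeR's quasi-likelihood test, 0 had an adjusted p under 0.05, and the lowest adjusted p was 0.9996. At an unadjusted p under 0.05 there were 367 genes, fewer than the 907 that chance alone gives. A count below chance can come from a test that is too cautious for these libraries, so 0 calls do not show that no gene differs. DESeq2 called 4 genes (Wnt7a, Wnt7b, Tinagl1 and Nppb, all higher with Ad-Cre, of which Nppb was too low to be tested with edgeR), and limma-voom with sample weights called 0. The weighted fit had 897 genes at an unadjusted p under 0.05. Its weights were 0.37 and 0.38 for the cardiac, 1.06 and 1.06 for the lung and 2.47 and 2.56 for the tail tip libraries. Genes named from here on in this comparison did not pass with edgeR. Those in the rest of this paragraph have the smallest unadjusted p among genes with a mean of at least 5 CPM and the same direction in all 3 origins, which was not asked of the list examples. Higher with Ad-Cre stood Tinagl1, a matrix protein gene (log2 fold change 1.11, SE 0.20), Krt80, a keratin gene (2.12, SE 0.58), Ano1, a calcium-activated chloride channel gene (1.61, SE 0.36), S100a7a (1.37, SE 0.28), Pdk4, a kinase gene of glucose oxidation (0.96, SE 0.22), and Acta1, the skeletal muscle actin gene (0.99, SE 0.24). Lama5, Slco2a1, Ampd3 and Prss23 were higher by 0.66, 0.50, 0.50 and 0.44. In the other direction stood Tnfsf18 (log2 fold change -1.49, SE 0.30), a cytokine gene read almost wholly in cardiac fibroblasts, Gap43 (-0.82, SE 0.21) and Cmpk2 (-0.81, SE 0.20), an interferon-induced gene. Fyb was at -0.79, Pde3b at -0.55, Apobec1 at -0.53, Cd68 at -0.60 and Cd14 at -0.57.

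The count of 0 did not hold under every setting. Without a filter on low counts 141 genes passed, and leaving out a library gave 11 genes (lung Ad-GFP), 12 (lung Ad-Cre), 23 (cardiac Ad-GFP), 28 (cardiac Ad-Cre), 107 (tail tip Ad-GFP) and 109 (tail tip Ad-Cre). In each of those fits the pair of the missing library carries no weight, so the calls rest on 2 origins.

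Of 29 gene lists, 11 passed camera with its preset correlation of 0.01 in the Ad-Cre comparison. None passed with an estimated correlation, where no adjusted p was under 0.617, but at 2 residual degrees of freedom hardly any list can. None passed with fry either, where no adjusted p was under 0.640. The estimated correlations were 0.68 for epithelial, 0.61 for immediate early, 0.56 for mitochondrially encoded and 0.53 for skeletal muscle genes. They were 0.36 for matrix, 0.28 for macrophage, 0.20 for stress response and 0.18 for interferon genes. Mesothelial markers had 0.09, p53 targets 0.02 and smooth muscle markers -0.02. Wherever the true correlation is above the preset 0.01, the p with the preset is too small. Macrophage and leukocyte markers were lower (adjusted p = 6.6e-12, and 0.617 with an estimated correlation). None of the 14 members passed over all genes, 2 were lower when adjusted over the list alone, and the complement gene C1qc had the largest log2 fold change, -0.89. Type I interferon response genes were lower (3.8e-07, and 0.617 with an estimated correlation), with 0 of 31 members called and Cmpk2 at -0.81, Oas3 at -0.76 and Irf7 at -0.61. Epithelial and keratinocyte markers were higher (8.0e-06, and 0.617 with an estimated correlation), with 4 of 6 measured members higher when adjusted over the list alone, among them Krt18 at 3.55, Krt8 at 2.68 and Dsp at 1.97. Mesothelial markers were higher (6.3e-05, and 0.617 with an estimated correlation). Over that list alone 4 members were higher and 1, Lrrn4, was lower, with Upk3b at 2.90, Upk1b at 2.87 and Lrrn4 at -1.75. These 3 genes had at most 2 reads in any lung or tail tip library, so their values rest on the cardiac pair. Krt19 belongs to both lists.

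Skeletal muscle lineage genes were also higher (adjusted p = 3.8e-05, and 0.617 with an estimated correlation), with 1 of 7 members higher when adjusted over the list alone. Des (1.02) and Acta1 (0.99) led that list, and Des also led the smooth muscle and pericyte markers (0.048, and 0.617 with an estimated correlation). The p53 and DNA damage targets were higher (0.043, and 0.617 with an estimated correlation), led by Perp at 3.55, a desmosome gene as well as a p53 target. Mitochondrially encoded genes were higher (0.029), and extracellular matrix structure (0.0023), immediate early genes (0.044) and the unfolded protein and integrated stress response (0.047) were lower, each with an adjusted p of 0.908 with an estimated correlation. No member of these last lists was called, over all genes or when adjusted over the list alone. The origins did not share these directions: in lung the median log2 ratio was -0.35 for mitochondrially encoded genes, 0.17 for the matrix, 0.37 for immediate early genes and 0.11 for the interferon response, and the stress response had 0.01 in both lung and tail tip. Lum (-0.91), Col3a1 (-0.47) and Dcn (-0.46) led the matrix list, and Klf2 (-0.51) and Ier2 (-0.50) the immediate early genes. Leaving out the cardiac pair left 3 lists (interferon, macrophage, and smooth muscle and pericyte), leaving out the tail tip pair left 6, and leaving out the lung pair gave 12.

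The remaining 18 lists did not pass camera in this comparison, and no member was called. They were the GATA family, cardiac developmental transcription factors, cardiomyocyte genes, lung mesenchyme genes, Hox genes of groups 1 to 8 and of groups 9 to 13, the myofibroblast contractile and TGF-beta response, adventitial fibroblast genes, inflammatory cytokines and NF-kB targets, mitosis, DNA replication, cholesterol synthesis, hypoxia and glycolysis, endothelial markers, the adipocyte lineage, cartilage and tendon, glia and melanocyte, and sex-linked genes. Within them Tcf21, a transcription factor gene of epicardial cells, was at -1.65 (SE 0.39), Hand2, a heart development gene, at -0.69 (SE 0.47) and Timp3 at 1.04 (SE 0.33). Tcf21 had no read in lung or tail tip fibroblasts. Every list that passed had a median, a mean and a camera direction of the same sign. Among those that did not, the signs differed for some, such as Hox groups 1 to 8 (median 0.05, mean 0.02, camera direction down) and adventitial fibroblast genes (median -0.20, mean 0.01).

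The question within each origin is how the library labelled Ad-Cre differs from its control. The spread of the ratios differed between origins. In tail tip fibroblasts 563 of 18143 genes differed at least 2-fold (277 higher, 286 lower), against 1395 in lung (884 and 511) and 3687 in cardiac fibroblasts (2042 and 1645). These counts depend on the prior count, and the tail tip count was larger with a prior count of 0.5, as given under the processing. The SD of the log2 ratios was 0.39, 0.54 and 1.01. Across genes, which are not independent replicates, the ratios of lung and cardiac fibroblasts had a Pearson correlation of -0.01 (0.01 with a prior count of 0.5) and a Spearman correlation of -0.11, those of lung and tail tip -0.08 and -0.10, and those of cardiac and tail tip 0.08 and 0.14. With a mean of at least 5 CPM the Pearson correlation was more negative for lung and cardiac and higher for cardiac and tail tip, as given under the processing. No p-value is given for any value within an origin.

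In lung fibroblasts, Krt7, Krt8, Itga3, Neil2 and Wnt7b stood higher in the library labelled Ad-Cre. Krt7 had 1 read in the control and 82 in the other library, a ratio of 93.1 (95% interval 16.3 to 3723), and Krt8 had 5 and 52 reads. Itga3, an integrin chain that binds laminin, was at 3.47 and 28.9 CPM (ratio 8.33, 6.76 to 10.4), Neil2, a DNA repair glycosylase gene, at 0.515 and 3.31 CPM, and the signalling ligand gene Wnt7b at 3.12 and 17.0 CPM. Ins2, Iapp and Scg2 stood lower. Ins2, an insulin gene, had 148 reads in the control and 10 in the library labelled Ad-Cre (ratio 0.0767, 0.0360 to 0.145), and shares sequence with Ins1. Iapp, which encodes amylin, had 50 and 3 reads, and Scg2, a secretory granule gene, 77 and 7. The pseudogenes Rpl19-ps6 (53 and 10 reads) and Ap3s1-ps1 (52 and 11 reads) share sequence with their parent genes, so their counts are uncertain.

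Cardiac fibroblasts had the widest spread of ratios, and the heat shock genes Hspa1a and Hspa1b are named among the lower genes. Hspa1a was at 385 CPM in the control and 3.57 CPM in the library labelled Ad-Cre (control over Ad-Cre 108, 89.2 to 131), and Hspa1b at 676 and 17.0 CPM (39.8, 36.4 to 43.5). The coding sequences of these stress-induced chaperone genes are nearly identical, so the split between them is uncertain. Cecr2, Myrfl and Chkb had 56, 53 and 52 reads in the control and 0 in the other library, so the control was at least 17.5-fold, 16.6-fold and 16.3-fold higher, with 3 reads as the floor of a library at 0. In cardiac fibroblasts 116 genes had 0 reads in a library and at least 20 in the other, against 2 in lung and 0 in tail tip. The cardiac libraries had 23120 and 22665 genes with a read, against 25234 to 27267 in the others. The lower bounds given for this pair cover counting error only and may not hold if few distinct molecules were read. Higher in the library labelled Ad-Cre were Aqp3, a water and glycerol channel gene (0 and 515 reads, at least 183-fold), Krt7 (8 and 768 reads, ratio 102, 51.6 to 238), Vnn1 (6 and 283 reads), Wnt7a (10 and 411 reads, ratio 43.8, 23.6 to 92.0) and Hoxc13, a posterior Hox gene that was at 51.0 CPM in tail tip control cells (0 and 81 reads in cardiac, at least 28.8-fold). The mitochondrial share of counts was 1.70% in the cardiac control and 2.38% in the library labelled Ad-Cre.

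In tail tip fibroblasts Ins2, Scg2 and Iapp stood the other way round from lung. Ins2 had 25 reads in the control and 279 in the library labelled Ad-Cre (ratio 10.7, 7.11 to 16.8), Scg2 12 and 181 (14.5, 8.09 to 28.6), Pcsk2, a prohormone convertase gene, 6 and 94 (15.0, 6.66 to 42.0), Iapp 13 and 93 (6.87, 3.83 to 13.4) and Chga, the chromogranin A gene, 13 and 53 (3.92, 2.11 to 7.83). Lower were Scand1 (838 and 25 reads, control over Ad-Cre 34.9, 23.5 to 54.2), B3gnt2 (56 and 5), Cebpb, a transcription factor gene of inflammation and fat cell differentiation (2065 and 290, 7.41, 6.55 to 8.41), the mitochondrial ribosome gene Mrps34 (399 and 65) and Adnp (147 and 26).

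Gene lists were placed by the percentile of their median log2 ratio among 10000 random lists of matched expression, which describes these libraries and is no test. Expression was matched over all 6 libraries and not within the origin. A list little read in an origin may therefore be set against genes that are better read there. Outside the central 95% lay 9 lists in lung, 10 in cardiac and 11 in tail tip fibroblasts. Macrophage and leukocyte markers were at percentile 0 in all 3 origins, with median log2 ratios of -0.42, -0.63 and -0.24 in lung, cardiac and tail tip. Their levels were far lower in lung than in tail tip (median log2 fold change -10.75 over the list). The lung ratios thus rest mostly on few reads, and the lung percentile is uncertain. Immediate early genes had medians of 0.37 (percentile 100) in lung, -0.61 (0) in cardiac and -0.21 (0) in tail tip fibroblasts. Mitochondrially encoded genes had -0.35 (0.01), 0.65 (100) and 0.24 (100). Matrix genes had 0.17 (99.75), -0.47 (0) and -0.08 (0.17). Interferon response genes had -0.51 in cardiac and -0.20 in tail tip fibroblasts, both at percentile 0, and 0.11 (95.9) in lung. Epithelial markers had 1.00 (99.93) in lung and 2.44 (99.99) in cardiac fibroblasts and 0.03 (60.31) in tail tip.

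Some lists stood apart in fewer origins. The GATA family was at 0.49 (99.93) in lung fibroblasts and within the central 95% in cardiac (-0.23) and tail tip (-0.11). Cardiac developmental transcription factors were at -0.50 (0.1) and the myofibroblast contractile and TGF-beta response at -0.42 (0.07) in cardiac fibroblasts, as was the unfolded protein and integrated stress response at -0.32 (1.17). Mesothelial markers were at 1.59 (100) in cardiac and 0.42 (99.99) in tail tip fibroblasts. Members such as Upk3b, Upk1b and Lrrn4 had almost no reads in tail tip cells, so the tail tip percentile is uncertain. Of 8 members there, 0 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. Skeletal muscle lineage genes were at 0.82 (99.48) in lung and at 1.05 in cardiac fibroblasts, just inside the central 95% (97.32), and smooth muscle markers at 0.38 (99.88) in lung. In tail tip fibroblasts mitosis genes were at -0.11 (0.01), p53 targets at 0.12 (99.89), adventitial genes at 0.15 (99.7), adipocyte genes at -0.45 (0.06) and cholesterol synthesis at 0.09 (98.9), against -0.13 (0.95) for cholesterol synthesis in lung.

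**Figure D3:**
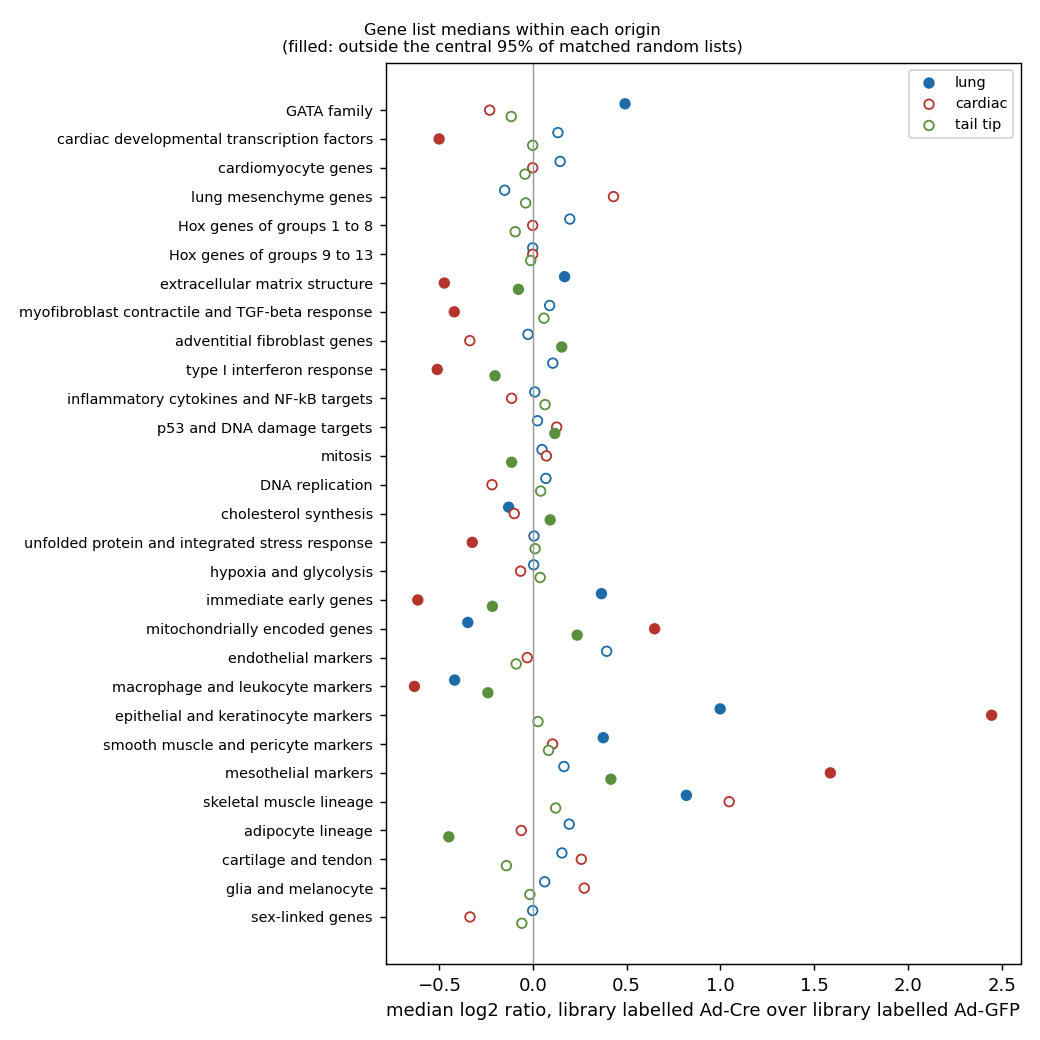
Median log2 ratio of the library labelled Ad-Cre over its control (x axis) for each gene list (y axis) in lung, cardiac and tail tip fibroblasts; each point is a list in 1 pair of libraries, and filled points lie outside the central 95% of matched random lists. Macrophage markers lie below 0 in all 3 origins (-0.42, -0.63 and -0.24), and immediate early genes lie above 0 in lung and below 0 in the others.

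The origins were compared next, with the 2 libraries of an origin as its replicates. Nothing in the labels says that they come from separate cultures or animals, so p-values measure the spread between these libraries only. Cardiac fibroblasts differed from lung fibroblasts in heart development genes, Hox genes, matrix genes and markers of other cell types. Tcf21 had 1148 and 338 reads in the cardiac libraries (control first) and 0 in lung. Tbx20, a cardiac T-box gene, was 87.4-fold higher as a ratio of summed normalised reads, and its log2 fold change fitted by the model was 6.40 (SE 0.26). Hand2 had 857 and 370 reads against 5 and 8 in lung, while Gata4 was higher by 3.14 (SE 0.18) and Gata6 by 2.25 (SE 0.38) on the log2 scale. The Hox genes Hoxc6 and Hoxb7, which set position along the body, had 992 and 979 reads in lung and 0 in cardiac fibroblasts, at least 381-fold and 376-fold more in lung. Macrophage genes were at far higher levels in cardiac cells, where Lyz2, the lysozyme gene, had 26527 and 14685 reads against 39 and 11 in lung.

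In this comparison 3774 genes were higher and 3193 lower in cardiac than in lung fibroblasts (edgeR, adjusted p under 0.05), and 18 of 29 lists passed camera. Below, each list has its camera adjusted p, followed by the adjusted p with an estimated correlation. Of the cardiac developmental transcription factors, 10 of 18 were higher and 4 lower (0.029, and 0.567). Of the Hox genes of groups 1 to 8, 16 of 18 were lower (1.2e-10, and 0.377). Matrix genes were mostly higher in cardiac cells, 18 of 22 against 3 lower (9.6e-06, and 0.405), with Postn, the periostin gene, higher by 7.35 (SE 0.27) and Dcn, the decorin gene, lower at -3.00 (SE 0.24). Of the p53 and DNA damage targets 17 of 22 were higher (2.2e-08, and 0.377), among them Gdf15 at 6.97 and Eda2r at 5.69. Mitosis genes were lower for 15 of 20 (9.6e-06, and 0.377) and replication genes for 16 of 21 (4.0e-07, and 0.377), with Mki67 at -1.39 and Mcm7 at -1.45. Macrophage markers were higher for 13 of 14 (1.2e-10, and 0.377), mesothelial markers for 6 of 8 with 1 lower (0.0047, and 0.377) and sex-linked genes for 5 of 5 (3.7e-05, and 0.377). With an estimated correlation none of these lists passed, which at 2 residual degrees of freedom hardly any list can. The p53 targets had an estimated correlation of 0.0177, near the preset 0.01, and still an adjusted p of 0.377. Most other lists given here had higher estimates: macrophage markers 0.51, matrix 0.34, mitosis 0.27 and Hox groups 1 to 8 0.25. Cardiac developmental factors had 0.22, replication 0.17, mesothelial markers 0.08 and sex-linked genes -0.18. Wherever the true correlation is above the preset, the camera p with the preset is too small. Counts adjusted over the list alone were the same except for mitosis (17 lower) and replication (19 lower).

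Cardiac and tail tip fibroblasts differed in interferon, cell cycle and positional genes. Interferon response genes were lower in cardiac cells for 31 of 31 members, with Ifit1, an interferon-induced RNA-binding protein gene, at 3.63 CPM in cardiac and 360 CPM in tail tip cells. Mitosis genes were higher in cardiac cells for 20 of 20 members and replication genes for 21 of 21, with Ccnb1, the cyclin B1 gene, higher by 3.18 (SE 0.20) and Tyms, the thymidylate synthase gene, by 2.07 (SE 0.15). The posterior Hox genes of groups 9 to 13 were lower for 11 of 11, and Hoxc11 had 1105 reads in tail tip and 0 in cardiac cells, at least 358-fold more. GATA family genes were higher in cardiac cells for 6 of 6, where Gata6 was higher by 8.28 (SE 0.55).

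In total 2816 genes were higher and 3261 lower in cardiac than in tail tip fibroblasts (edgeR), and 17 lists passed camera. The list tests gave an adjusted p of 4.4e-27 for the interferon response, 1.7e-20 for mitosis, 2.7e-12 for replication, 1.7e-10 for Hox groups 9 to 13 and 1.6e-09 for Hox groups 1 to 8 (16 of 18 lower). With an estimated correlation the lowest adjusted p of any list was 0.254, so none passed, which the few residual degrees of freedom allow for hardly any list. Macrophage markers were lower for 12 of 14 (6.0e-09, and 0.254 with an estimated correlation), with Adgre1 at -3.89 (SE 0.23). Cardiac developmental transcription factors were higher for 13 of 18 and lower for 2 (2.5e-06, and 0.280). Inflammatory cytokines and NF-kB targets were lower for 15 of 23 and higher for 5 (0.0027, and 0.254), among them Saa3 at -8.57 and Ccl7 at -4.74. Matrix genes were lower for 11 of 22 and higher for 4 (0.011, and 0.574), and hypoxia and glycolysis genes lower for 11 of 20 (0.00042, and 0.280). Adjusted over the list alone, 13 macrophage markers, 17 Hox genes of groups 1 to 8, 12 matrix genes and 13 hypoxia genes were lower and 6 inflammatory genes higher, and the other counts stayed. The total depended on single libraries: it was 3110 without the tail tip Ad-GFP library, 3338 without the tail tip Ad-Cre library and 9208 without the cardiac Ad-Cre library.

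Lung and tail tip fibroblasts differed in the most genes. All 31 interferon response genes were lower in lung, with Ifi44 at -7.31 (SE 0.23) and Irf7, a master regulator of the response, at -6.71 (SE 0.32). All 20 mitosis genes and all 21 replication genes were higher in lung, with Mki67, the Ki-67 proliferation gene, higher by 3.68 (SE 0.17) and Mcm2 by 2.73 (SE 0.16). Matrix genes were lower in lung for 20 of 22 and higher for 1, with Postn at -5.35 (SE 0.25), the collagen crosslinking gene Lox at -5.11 (SE 0.20) and Col6a2 at -5.07 (SE 0.22). Macrophage genes were lower for 13 of 14, and the complement gene C1qb had 0 reads in lung and 2744 in tail tip fibroblasts, at least 772-fold more.

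Here 4050 genes were higher and 5125 lower in lung (edgeR), and 15 lists passed camera, with adjusted p of 4.0e-18 for the interferon response, 4.0e-17 for mitosis, 1.3e-13 for replication, 4.3e-11 for macrophage markers and 1.2e-08 for the matrix. With an estimated correlation the lowest adjusted p was 0.331, so none passed, which the few residual degrees of freedom allow for hardly any list. The p53 targets were lower for 17 of 22 and higher for 1 (0.00020, and 0.331 with an estimated correlation), mitochondrially encoded genes, whose reads can be shared with nuclear copies, higher for 11 of 13 and lower for 1 (0.0026, and 0.567), GATA family genes higher for 6 of 6 (0.00043, and 0.485) and sex-linked genes lower for 5 of 5 (0.00020, and 0.331). Adjusted over the list alone these counts were the same. Without the tail tip Ad-GFP library 5995 genes passed in place of 9175.

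Genes that marked an origin were higher there than in both others. There were 2106 such genes for lung, 859 for cardiac and 2438 for tail tip fibroblasts, and 2858, 776 and 1837 were lower than in both others. Where a fold moves by over 1.5 times when a library is left out, reads per library are given in its place, the control first. Lung fibroblasts were marked by Hsd3b6, a steroid dehydrogenase gene (272-fold over tail tip), Il33, an alarmin cytokine gene (7984 and 3126 reads, against 34 and 17 in cardiac and 16 and 17 in tail tip), Klra4 (140-fold over cardiac and 663-fold over tail tip), the urea transporter gene Slc14a1 (128-fold over tail tip, with 1185 and 756 reads against 4 and 18 in cardiac), Dscam (613 and 600 reads, against 6 and 3 in tail tip) and Epb41l4a (58.2-fold over cardiac and 69.9-fold over tail tip). Mir7688 was at least 217-fold over tail tip cells, and Prl2c2 had 11332 and 4327 reads against 196 and 21 in cardiac and 112 and 151 in tail tip. It has near-identical copies, which leaves its count uncertain. The call of Prl2c2 was lost without the lung Ad-GFP library (adjusted p = 0.341) and without the lung Ad-Cre library (0.325), and held in its other alternatives (at most 0.00285).

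Cardiac fibroblasts were marked by Tcf21 and by the mesothelial genes Lrrn4 (1048 and 288 reads, against 0 in lung and tail tip), Upk1b (184 and 1269, against 0 in tail tip) and Upk3b (95 and 878, against 0 in lung). Gdf6, a bone morphogenetic protein gene, was 311-fold over tail tip and at least 1750-fold over lung, Gucy1a1, a guanylate cyclase subunit gene, at least 545-fold over lung. Nrk had 2482 and 2029 reads against 1 and 10 in tail tip, and Ptprb 15546 and 9367 against 0 and 6 in lung. Tail tip fibroblasts were marked by Hoxc11, by Thbs4, a thrombospondin gene of tendon (164964 and 156779 reads, against 39 and 0 in lung), by Prg4, the lubricin gene (2708-fold over cardiac, with 61811 and 74718 reads against 29 and 5 in lung), by Cilp, a cartilage matrix gene (2145-fold over lung, with 15068 and 12885 reads against 8 and 17 in cardiac), by Pcp4l1 (8576 and 8215 reads, against 12 and 0 in cardiac) and by Dio3, which inactivates thyroid hormone (at least 644-fold over lung). H2-M2 (at least 266-fold over cardiac and 231-fold over lung) belongs to a family of similar genes, so its count is uncertain, and Tnfaip8l3 was at least 217-fold and 189-fold higher. With DESeq2 the calls of Upk3b, Hoxc11, H2-M2 and Tnfaip8l3 were lost (adjusted p of 0.0931, 0.0517, 0.0629 and 0.0714), and held in their other alternatives, with adjusted p of at most 0.00785, 0.000566, 0.000626 and 0.000868. The call of Thbs4 was lost without the cardiac Ad-GFP library (0.169) and held otherwise (at most 0.00678).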

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

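The tests of endocrine RNA, of a response to Ad-Cre and of exchanged lung labels were all chosen after the result was seen. Among 76 named genes, 8 had log2 ratios of Ad-Cre to Ad-GFP that were at least 2-fold and opposite in a pair of origins, and 4 gene lists lay outside the central 95% of matched random lists on opposite sides. With 1 library per group these differences were not tested. All directions follow the labels, although Gata4 RNA was not lower in the libraries labelled Ad-Cre.

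Endocrine genes differed between tail tip and both other origins. The log2 ratio in tail tip minus that in lung was 6.82 for Ins2, 6.64 for Scg2, 6.03 for Pcsk2, 5.89 for Iapp and 4.91 for Chga. In tail tip minus cardiac it was 7.23 for Pcsk2, 6.14 for Ins2 and 5.11 for Iapp. These 3 genes had 26, 13 and 10 reads in the cardiac control and 0 in the other cardiac library. Chkb had a difference of -5.70 in cardiac minus lung, and the pseudogenes Ap3s1-ps1 and Rpl19-ps6 had 3.85 and 3.55, from counts of at most 53 reads that can be shared with their parent genes.

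Medians of gene lists also went opposite ways. Immediate early genes differed by -0.98 in cardiac minus lung and by -0.58 in tail tip minus lung. Mitochondrially encoded genes differed by 1.00 and 0.58, and extracellular matrix genes by -0.64 and -0.25, in the same order. Cholesterol synthesis differed by 0.22 in tail tip minus lung.

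Of a list of islet markers 8 genes were at least 2-fold lower with Ad-Cre in lung and at least 2-fold higher in tail tip, and 0 moved at least 2-fold the same way in both, but 5 of the 8 had themselves shown the pattern, so a response of fibroblasts to Ad-Cre stays open. RNA or reads of an endocrine sample in the lung Ad-GFP and tail tip Ad-Cre libraries may be their source, which also stays open. The 8 genes, taken because they were raised in both, stood in ratios between 1.31 and 2.51 between those libraries (SD 0.35 on the log2 scale, against a median of 1.51 over all 40320 pairings of their levels, one-sided exact permutation p = 0.000446). That p shows only that the levels of these 8 genes go together gene by gene. Any shared endocrine expression would give this, so it does not tell the explanations apart. Ins2, the most abundant, was at 5.08 and 8.43 CPM. Of the 20 list genes 12 were measured, and Mafa, Pax6, Neurod1 and Rbp4, which were not raised in both libraries, had ratios of 2.64, 0.349, 6.60 and 15.8. For the gene lists exchanged lung labels stay open. The exchange gave 1064 genes at an unadjusted p under 0.05 with edgeR, against 367 as labelled and 907 by chance. Exchanging the cardiac labels gave 280 and the tail tip labels 257. As labelled, 2 lists lay on the same side in lung and cardiac and 3 on opposite sides. In lung and tail tip these counts were 1 and 4, and in cardiac and tail tip 6 and 0. The lists on the same side in lung and another pair leave this undecided. A different response of each origin also stays open and was not tested.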

How the results depend on the processing

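limma-voom with sample weights and list members with at least 10 reads were chosen after the data had been seen. By replicate number, no paired analysis was possible because the groups share only number 1, so origin was the block. Without the origin block, the setting with no replicate block, 0 genes differed between the viruses with edgeR, as with it (17 and 367 at an unadjusted p under 0.05).

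Counts of genes or lists were labelled the same within 1.5-fold of the main count, so that label covers large changes. The tolerance was 0.05 for correlations, 5 percentage points for the share of variance and the counting interval for Gata4 ratios. Of the results that answer a comparison, 78 alternative values were the same by these rules, 9 stronger, 10 weaker and 5 moved. For named genes, labelled by direction and side of the threshold, 580 alternatives were the same, 25 stronger, 7 weaker and 0 reversed. The cause was not tested unless stated. Between Ad-Cre and Ad-GFP, DESeq2 called 4 genes, the fit with no filter beyond 1 read 141 and limma-voom 0. Leaving out a library gave from 11 (lung Ad-GFP) to 109 (tail tip Ad-Cre), with 12 (lung Ad-Cre), 23 (cardiac Ad-GFP), 28 (cardiac Ad-Cre) and 107 (tail tip Ad-GFP) between. Such a fit has fewer libraries, and a left-out library's partner is assumed to vary like the other groups. Cardiac against tail tip ran from 3110 genes (without tail tip Ad-GFP) to 9208 (without cardiac Ad-Cre), with 3338 without tail tip Ad-Cre. Lung against tail tip ran from 5995 (without tail tip Ad-GFP) to 12560 (without cardiac Ad-Cre), and cardiac against lung from 5038 to 10065. limma-voom gave 6986 for cardiac against lung, 6766 for cardiac against tail tip and 12051 for lung against tail tip.

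With an estimated correlation 0 gene lists passed for the virus, 0 for cardiac against lung, 0 for cardiac against tail tip and 0 for lung against tail tip. That setting has only the 2 residual degrees of freedom, so hardly any list can pass it. With fry, which does not compare a list with other genes, 0 passed for the virus, 19 for cardiac against lung, 21 for cardiac against tail tip and 17 for lung against tail tip. Without the lung pair 12 virus lists passed, without the cardiac pair 3 and without the tail tip pair 6. The cardiac log2 ratio of Gata4 was 0.11 with library totals only, in place of 0.03. With a prior count of 0.5, 965 tail tip genes differed at least 2-fold, since a lower prior widens ratios of low counts. With a mean of at least 5 CPM the correlation was -0.0743 between lung and cardiac and 0.21 between cardiac and tail tip. With library totals only, the median log2 difference of all genes was -0.11 for cardiac minus tail tip and -0.12 for lung minus tail tip, in place of -0.06 for both. Origin held 90.1% of the variance over all tested genes. With list members of at least 10 reads, adventitial genes (percentile 0.4), Hox groups 1 to 8 (0.04) and inflammatory genes (2.31) also lay outside the central 95% in cardiac fibroblasts. Depth limits genes of a few reads, where 0 reads allow up to 3 counts.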

Other observations

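All tests in this part were chosen after the result was seen, except that of zero counts among genes below 5 CPM.

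Sex-linked genes separated lung fibroblasts from the others. Xist, the RNA that silences an X chromosome, had a mean of 0.747 CPM in lung, 778 CPM in cardiac and 1054 CPM in tail tip fibroblasts. The Y-linked gene Ddx3y was at 0.0367, 22.0 and 15.0 CPM, so cardiac and tail tip fibroblasts held reads of both genes and lung fibroblasts few of either. Eif2s3y, another Y-linked gene, had 0 reads in both lung libraries and 223 to 345 in each of the others.

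Genes tied to p53 are named here after their values were seen. The fixed list of p53 and DNA damage targets passed camera with its preset correlation in each comparison of origins (adjusted p = 2.2e-08, 0.012 and 0.00020). It did not pass with an estimated correlation (adjusted p = 0.377, 0.280 and 0.331), a setting that hardly any list can pass at 2 residual degrees of freedom. Cdkn1a, a cell cycle inhibitor gene and p53 target, had a mean of 56.1 CPM in lung, 534 CPM in cardiac and 403 CPM in tail tip fibroblasts. Ccng1 was at 47.1, 916 and 516 CPM. Trp53, which encodes p53, was at 256 CPM in lung against 136 and 131 CPM, a log2 fold change of -0.92 (SE 0.19) in cardiac minus lung with an edgeR adjusted p of 0.00839. Cdkn2a was at 60.6 CPM in lung, 10.3 CPM in cardiac and 42.3 CPM in tail tip fibroblasts.

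A set of 53 genes was at least 2-fold higher in the libraries labelled Ad-Cre of both lung and cardiac fibroblasts. This exceeds 10000 pairings of genes of similar expression (mean 29.4, highest 50), but 31 genes were up in lung and down in cardiac (mean 23.7) and 28 the reverse (mean 19.0), and if directions were independent among the 124 genes changed in both, 54.9 would be up in both, so independent directions could give the set and stay open. Their medians of 1.34 in lung and 2.26 in cardiac follow from how the members were chosen, and only tail tip was free to differ. Of the 40 members measured there, 0 were up 2-fold, and the median log2 ratio was -0.0055 (quartiles -0.20 and 0.31). In that 1 pair of libraries this argues against a common change of at least 2-fold for these members. A smaller common change, or members up in both by independent changes, stay open. RNA or cells of another source may have been added to both libraries, which stays open: the log2 ratio of added CPM had an SD of 1.24 over 24 members, between the values set for and against it. Loss of Gata4 function where it is expressed could also give the set and stays open, as the cardiac log2 ratio of Gata4 was 0.0267 and the deleted part is not given.

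Ratios spread most widely in the cardiac pair, with an SD of 1.01. Fewer reads were argued against, since the smaller cardiac library held 30.0344 megareads and the smallest of the others 26.1703. Few distinct RNA molecules could widen low counts: of genes at 1 to 5 CPM elsewhere, 0.979% had no read in exactly 1 cardiac library, against 3.10% in lung and 0.526% in tail tip, and 116 genes had 0 reads in a cardiac library and at least 20 in the other, against 2 and 0, so this stays open. At 100 CPM and more the robust SD was 0.379, above the 0.139 that such a loss would leave, so it is not the whole cause. A difference in the response of cardiac fibroblasts was not tested.

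With edgeR 0 genes differed between the viruses (367 at an unadjusted p under 0.05, 4 with DESeq2 and 0 with limma-voom). The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05, and the highest other split called 4086 genes. That split parts the cardiac pair alone and the real one all 3 pairs, so its count points only to a structure of the samples, the difference between both cardiac libraries.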
